A study of Homo sapiens with 105 samples.

How the data were processed

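MCF-7 cells in charcoal-stripped serum were infected with control adenovirus or with adenovirus carrying estrogen receptor beta at a multiplicity of infection of 20 for 48 h, and then treated for 4 h or 24 h, per the labels' protocols. RNA from each dish was hybridized as biotin-labelled cRNA to 1 Affymetrix human expression array. The deposited values are 1 log2 expression value per probe set and array, background-corrected and normalized by the authors with GCRMA, per the submitters' processing notes, which give no version. The notes do not say whether all arrays were normalized in a single run. The scale was read from the values, since the notes do not state it: each array held 22283 values that ran as log2 values of a scan do and were not centred per probe set. The scanner files were not part of the data.

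Groups came from the labels. They placed 104 of 105 arrays in 27 groups of virus, treatment and time. The title and the description of 1 array name different treatments, and it entered no comparison. The replicate numbers in the labels are called biological replicates there. At 24 h they run to 9 in some groups, and whether the arrays numbered 4 and up were a later set is not stated. The replicate numbers were not used to pair the samples. At 4 h 76 of 237 pairs of same-numbered arrays from different groups correlated above 0.1 in their deviations from the group means, and 15 of 39 arrays correlated best with their own number. At 24 h these were 154 of 299 pairs and 17 of 65 arrays.

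Of the 22283 probe sets, 68 were Affymetrix controls and were left out. The platform table named 1 gene symbol for 19071 probe sets, several for 1043 and none for 2169, and probe sets with several or none were not used. A gene was represented by its probe set with the highest mean over all arrays with a group, which gave 11963 genes. Of these, 5005 had a log2 value above 5 in at least 3 arrays and were tested. For 921 pairs of a named gene and a comparison, another probe set of the gene passed the filter too. It went the opposite way at an unadjusted p under 0.05 in 10 of them, among them pairs of ESR1 and VDR in AdERb cells at 24 h, which are not quoted.

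Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit of all 104 arrays, with a mean for each group and an additive term for the numbering set (24 h arrays numbered 4 and up against 1 to 3). The fit had 76 residual and 79.7 total degrees of freedom. P-values are two-sided and adjusted by Benjamini-Hochberg over the 5005 genes within each comparison, with a threshold of 0.05. There were 45 comparisons: estrogen receptor beta without ligand at each time, each ligand against vehicle, the interaction of each ligand with the virus, the compounds against each other, and ICI 182,780 plus a compound against that compound. The interactions are the response in AdERb cells minus that in Ad cells. Comparisons between compounds also give 95% intervals from the moderated standard errors. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the plots.

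Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists within a comparison, and again with a correlation estimated from the residuals. A list needed at least 5 tested members. The 20 lists held 492 genes, of which 438 were on the array: estradiol-induced, estradiol-repressed, DNA replication, mitosis, CDK inhibitors and p53 targets, apoptosis regulators, interferon response, TGF-beta and BMP signalling, immediate early response, aryl hydrocarbon receptor targets, nuclear receptors and coregulators, cholesterol biosynthesis, unfolded protein response, ribosome biogenesis, glycolysis and hypoxia, luminal epithelium, basal epithelium, fibroblast, leukocyte, and epithelial invasion and semaphorin guidance. The interferon response, fibroblast, basal epithelium and leukocyte lists had 4, 4, 3 and 0 tested members and gave no test. The estradiol-repressed list and the TGF-beta and BMP signalling list share 4 tested members. Over all comparisons 248 list tests passed with the preset correlation, and 85 of them passed with an estimated correlation as well.

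The groups, the test, the lists, the level filter, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule named a panel of receptor and cell cycle genes, the 8 largest increases and decreases in 4 lead comparisons (estrogen receptor beta without ligand at 24 h, estradiol in Ad cells at each time and 300 nM genistein in AdERb cells at 24 h), the 3 largest in every other comparison, and up to 4 changed members of each list. A gene named in any comparison could be quoted in others. In ranking, every array of the first group had to lie on the same side of the second group's mean, except for interactions. The rule named 2037 pairs of gene and comparison past the threshold, too many to print. Those quoted were picked among the pairs that kept their call under every alternative. Pairs whose group means both lay under a log2 value of 5, and the size of the ESR2 difference, are not quoted. PGR, PDZK1 and E2F1 of the panel did not pass the level filter.

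The method was tested on simulated data: normal noise with each gene's residual spread around its mean, with 200 of 5005 genes changed by known amounts. For vehicle in AdERb against Ad cells at 24 h, 92.5% of genes changed by 1 log2 unit were called, and 52.2% of those changed by 0.5, with 7 false calls. For estradiol in Ad cells at 4 h these shares were 77.6% and 20.9%, with 6 false calls.

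Alternatives changed a single choice each: no level filter, quantile normalization between arrays, no numbering set term, replicate number as a block, only the arrays of the compared groups, the mean of all probe sets of a gene, only arrays numbered 1 to 3, only arrays numbered 4 and up, each array of a group of 2 to 5 left out in turn, an estimated inter-gene correlation, and vehicle arrays split between the ligands. A term for the signal of the hybridization controls, and leaving out the 6 arrays with under 3500 genes above a log2 value of 5, were added later.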

Results

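Gene expression was measured in MCF-7 cells, a human breast cancer line that carries estrogen receptor alpha, after infection with a control adenovirus (Ad cells) or with an adenovirus that expresses estrogen receptor beta (AdERb cells). The cells received vehicle, estradiol at 6 nM, genistein at 6 nM or at 300 nM, or S-equol at 300 nM for 4 h or 24 h. Further cells received ICI 182,780, an antagonist of both receptors, at 3 µM together with genistein or S-equol at 300 nM. Genistein is a soy isoflavone with a ketone and a hydroxyl group that S-equol, an isoflavan, lacks. The labels put all arrays but 1 into 27 groups, 39 arrays at 4 h and 65 arrays at 24 h. At 4 h every group held 3 arrays, except 300 nM genistein in Ad cells, ICI plus genistein in Ad cells and S-equol in AdERb cells with 2 arrays each. At 24 h the Ad groups held 6 arrays, except estradiol with 5, 6 nM genistein with 3 and ICI plus S-equol with 2. The AdERb groups at 24 h held 6 arrays with vehicle and with estradiol, 9 with 6 nM genistein, 4 with 300 nM genistein, 4 with S-equol and 2 with ICI plus genistein. ICI plus S-equol had no AdERb arrays at 24 h. Each array gave a log2 GCRMA value per probe set, and 5005 genes passed the level filter. Between 3275 and 4283 genes per array lay above a log2 value of 5, with a median of 3939.5. Under 3500 genes did so on 6 arrays, all from AdERb cells at 24 h, 2 with estradiol, 3 with 6 nM genistein and 1 with 300 nM genistein. At 24 h some groups held arrays numbered 4 and up besides those numbered 1 to 3. Counts within each of these numbering sets stand beside the 24 h counts where each group had more than 1 such array. The number of arrays limits the precision: the median standard error of a difference was 0.16 log2 units between groups of 6 and 0.23 between groups of 3.

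ESR2, the gene of estrogen receptor beta, checked the virus labels. Its median log2 value was 12.46 on the 51 AdERb arrays (11.23 to 13.98) and 2.55 on the 53 Ad arrays (2.40 to 5.99), and none of these lay nearer to the median of the other virus. On the 1 Ad array at 5.99 the other 2 ESR2 probe sets that detect the transgene read 2.62 and 2.31, close to background. Values after a gene name are log2 differences ± SE from limma, with an adjusted p under 0.05 unless stated. A list result counts members past that threshold, and its p uses the preset correlation. An estimated correlation gave larger p-values, printed mainly where they failed. Genes named for the size of their change, interactions aside, lay, on every array of the first group, on the same side of the second group's mean. Of the 120 differences quoted between 2 groups, 77 had 1 group mean under 5, where a GCRMA value is close to background. Their size and rank are uncertain. Of the 17 interactions quoted for single genes, 12 had such a group.

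Without ligand, 836 genes differed at 24 h, 434 higher and 402 lower in AdERb cells (6 arrays against 6). Within arrays numbered 1 to 3 and those numbered 4 and up, 681 and 418 genes did so. With the hybridization control signal as a term the split was 298 and 675, mostly lower. Besides ESR2, the largest increases included TFF1 (3.55 ± 0.27), DHRS2 (3.23 ± 0.37), ACTG2 (3.14 ± 0.25), ABCG2 (2.79 ± 0.26) and MICB (2.67 ± 0.24). Of the estradiol-induced list, 15 of 30 members rose and 0 fell (17 and 0 adjusted over the list alone, median 0.565, adjusted p = 8.73e-14). These included CTSD (2.39 ± 0.17), IGFBP4 (2.37 ± 0.23) and CXCL12 (1.64 ± 0.31). With an estimated correlation the list had a camera adjusted p of 0.0374. Of the CDK inhibitors and p53 targets, 7 of 10 members rose and 1 fell (7 and 1 adjusted over the list alone, median 0.745, adjusted p = 9.36e-06, adjusted p = 0.103 with an estimated correlation). FAS (2.62 ± 0.29) and CDKN1A (0.67 ± 0.09) were higher. Of the mitosis list, 0 of 39 members rose and 14 fell (0 and 14 adjusted over the list alone, median -0.265, adjusted p = 6.89e-07, adjusted p = 0.312 with an estimated correlation). PTTG1 (-2.52 ± 0.34) and UBE2C (-2.29 ± 0.20) were among the largest decreases. FBN2 (-1.83 ± 0.21), ARNT2 (-1.56 ± 0.21) and INSR (-1.51 ± 0.27) fell too. Of the luminal epithelium list, 0 of 16 members rose and 8 fell (1 and 9 adjusted over the list alone, median -0.29, adjusted p = 0.000173, adjusted p = 0.103 with an estimated correlation).

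At 4 h of vehicle, 358 genes differed, 103 higher and 255 lower, or 221 and 210 after quantile normalization in AdERb cells (3 arrays against 3). The count was 192 and 211 without AdERb vehicle replicates 2 and 3 in turn. It was 226, 189 and 231 without Ad vehicle replicates 1, 2 and 3. TFF1 (3.13 ± 0.38), ACTG2 (2.36 ± 0.35), CXCL12 (1.97 ± 0.44) and CTSD (1.77 ± 0.25) were again higher, and DLX2 (-1.70 ± 0.28) and UBE2C (-1.37 ± 0.29) lower. Among estradiol-induced genes, 9 of 30 members rose and 0 fell (13 and 1 adjusted over the list alone, median 0.57, adjusted p = 2.04e-12, adjusted p = 0.061 with an estimated correlation).

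Cells with estrogen receptor alpha alone came next. After 4 h of estradiol in Ad cells, 510 genes differed, 296 higher and 214 lower (3 arrays against 3). HOXC6 (4.61 ± 0.41), PLAC1 (4.42 ± 0.52), SERPINB9 (4.26 ± 0.29), IL17RB (4.23 ± 0.61), IGFBP4 (3.78 ± 0.32) and TFF1 (3.71 ± 0.38) were among the largest increases. MMD (-3.59 ± 0.33), BIK (-3.03 ± 0.36), PDP1 (-2.97 ± 0.32), BLNK (-2.81 ± 0.43) and ID2 (-2.64 ± 0.26) were among the largest decreases. GREB1 (2.96 ± 0.49) and MYC (1.71 ± 0.20) rose too. Of the estradiol-induced list, 23 of 30 members rose and 0 fell (24 and 0 adjusted over the list alone, median 1.86, adjusted p = 9.05e-42). Of the ribosome biogenesis list, 9 of 19 members rose and 0 fell (13 and 0 adjusted over the list alone, median 0.47, adjusted p = 7.97e-09). Of the TGF-beta and BMP signalling list, 0 of 15 members rose and 8 fell (0 and 10 adjusted over the list alone, median -0.85, adjusted p = 2.66e-10). Of the estradiol-repressed list, 3 of 21 members rose and 10 fell (4 and 13 adjusted over the list alone, median -0.85, adjusted p = 1.45e-06, adjusted p = 0.111 with an estimated correlation).

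S-equol for 4 h changed 499 genes in Ad cells, 288 higher and 211 lower (3 arrays against 3). They included HOXC6 (4.36 ± 0.41), PLAC1 (4.30 ± 0.52), IL17RB (4.14 ± 0.61) and MMD (-3.66 ± 0.33). With 300 nM genistein 1001 genes differed, 331 higher and 670 lower, or 484 and 570 after quantile normalization (2 arrays against 3), and 484 did so without Ad 300 nM genistein replicate 2. The median of all genes was -0.11 in that comparison. HOXC6 (4.66 ± 0.45), SERPINB9 (4.60 ± 0.32) and TFF1 (3.86 ± 0.43) rose, and MMD (-3.75 ± 0.37), BIK (-3.56 ± 0.40) and CYP1A1 (-3.18 ± 0.18) fell. Among estradiol-induced genes, 24 of 30 members rose and 0 fell (24 and 0 adjusted over the list alone, median 1.76, adjusted p = 3.21e-42) with S-equol. With 300 nM genistein 23 rose and 0 fell (24 and 0 adjusted over the list alone, median 1.60, adjusted p = 4.03e-29). Genistein at 6 nM changed 17 genes at 4 h, 9 higher and 8 lower (33 and 14 after quantile normalization, 13 and 29 without the level filter, 3 arrays against 3). That count was 5, 5 and 11 without Ad 6 nM genistein replicates 1, 2 and 3 in turn. It was 8, 7 and 6 without the Ad vehicle replicates in the same order. TSKU (1.69 ± 0.29) rose. Of the estradiol-induced list, 5 of 30 members rose and 0 fell (13 and 2 adjusted over the list alone, median 0.54, adjusted p = 1.86e-16).

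After 24 h of estradiol in Ad cells, 2117 genes differed, 1128 higher and 989 lower (5 arrays against 6). The count was 2015 and 1200 within arrays numbered 1 to 3 and those numbered 4 and up. Among the largest increases were TFF1 (5.75 ± 0.28), IL17RB (5.39 ± 0.46) and the cell division genes CDC20 (5.13 ± 0.33), KIF2C (4.90 ± 0.26), KIF20A (4.57 ± 0.23) and KIF4A (4.57 ± 0.22). Among the decreases were IL1R1 (-4.63 ± 0.38), CLDN1 (-3.46 ± 0.40), L1CAM (-3.40 ± 0.23), CRIP2 (-3.16 ± 0.32) and CCNG2 (-2.65 ± 0.49). Among mitosis genes, 39 of 39 members rose and 0 fell (39 and 0 adjusted over the list alone, median 3.52, adjusted p = 7.35e-54). Of the DNA replication list, 20 of 21 members rose and 0 fell (20 and 1 adjusted over the list alone, median 2.66, adjusted p = 3.85e-20). PRIM1 (4.15 ± 0.32) and RRM2 (4.05 ± 0.41) were among them. Among estradiol-induced genes, 18 of 30 members rose and 1 fell (21 and 1 adjusted over the list alone, median 1.34, adjusted p = 7.18e-11). Of the ribosome biogenesis list, 17 of 19 members rose and 0 fell (18 and 0 adjusted over the list alone, median 0.88, adjusted p = 2.44e-09). The 3 lists that follow were lower as groups. In TGF-beta and BMP signalling 0 rose and 13 fell (0 and 13 adjusted over the list alone, median -1.15, adjusted p = 2.44e-09). In the estradiol-repressed list 4 rose and 17 fell (4 and 17 adjusted over the list alone, median -1.15, adjusted p = 9.55e-09). In the luminal epithelium list 0 rose and 13 fell (0 and 14 adjusted over the list alone, median -0.56, adjusted p = 2.18e-07).

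The other lists did not pass the camera test with estradiol in Ad cells at 24 h. Of the CDK inhibitors and p53 targets, 3 of 10 members rose and 5 fell (4 and 5 adjusted over the list alone). Among apoptosis regulators, 1 of 13 members rose and 6 fell (2 and 6 adjusted over the list alone). Among immediate early response genes, 4 of 15 members rose and 7 fell (4 and 8 adjusted over the list alone). Among aryl hydrocarbon receptor targets, 1 of 5 members rose and 2 fell (1 and 2 adjusted over the list alone). Among nuclear receptors and coregulators, 2 of 16 members rose and 6 fell (2 and 7 adjusted over the list alone). For cholesterol biosynthesis, 5 of 15 members rose and 4 fell (5 and 4 adjusted over the list alone). For the unfolded protein response, 7 of 15 members rose and 2 fell (8 and 2 adjusted over the list alone). For glycolysis and hypoxia, 4 of 17 members rose and 1 fell (4 and 1 adjusted over the list alone). For epithelial invasion and semaphorin guidance, 1 of 7 members rose and 3 fell (1 and 3 adjusted over the list alone). Their adjusted p ran from 0.0798 to 0.753.

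With 300 nM genistein for 24 h in Ad cells 2014 genes differed, 722 higher and 1292 lower, and with S-equol 1927 genes differed, 783 higher and 1144 lower (6 arrays against 6 in each). Within arrays numbered 1 to 3 and those numbered 4 and up, 2031 and 1045 genes differed with genistein and 2240 and 753 with S-equol. TFF1 rose in both, by 6.28 ± 0.27 with genistein and 6.27 ± 0.27 with S-equol. CDC20 (4.86 ± 0.32 and 4.80 ± 0.32) and KIF2C (4.56 ± 0.24 and 4.75 ± 0.24) followed. CRIP2 (-3.50 ± 0.31 and -3.29 ± 0.31) and IL1R1 (-3.27 ± 0.36 and -2.81 ± 0.36) fell. Of the mitosis list, 39 of 39 members rose and 0 fell (39 and 0 adjusted over the list alone, median 3.31, adjusted p = 2.18e-68) with genistein. With S-equol 39 rose and 0 fell (39 and 0 adjusted over the list alone, median 3.53, adjusted p = 2.57e-69). Genistein at 6 nM changed 111 genes, 97 higher and 14 lower (3 arrays against 6). CDC20 (3.64 ± 0.39), TFF1 (3.56 ± 0.34) and PRC1 (3.09 ± 0.43) rose. Among mitosis genes, 34 of 39 members rose and 0 fell (35 and 0 adjusted over the list alone, median 1.83, adjusted p = 1.19e-141) with 6 nM genistein. Of the DNA replication list, 16 of 21 members rose and 0 fell (18 and 0 adjusted over the list alone, median 1.23, adjusted p = 3.23e-41).

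**Figure D1:**
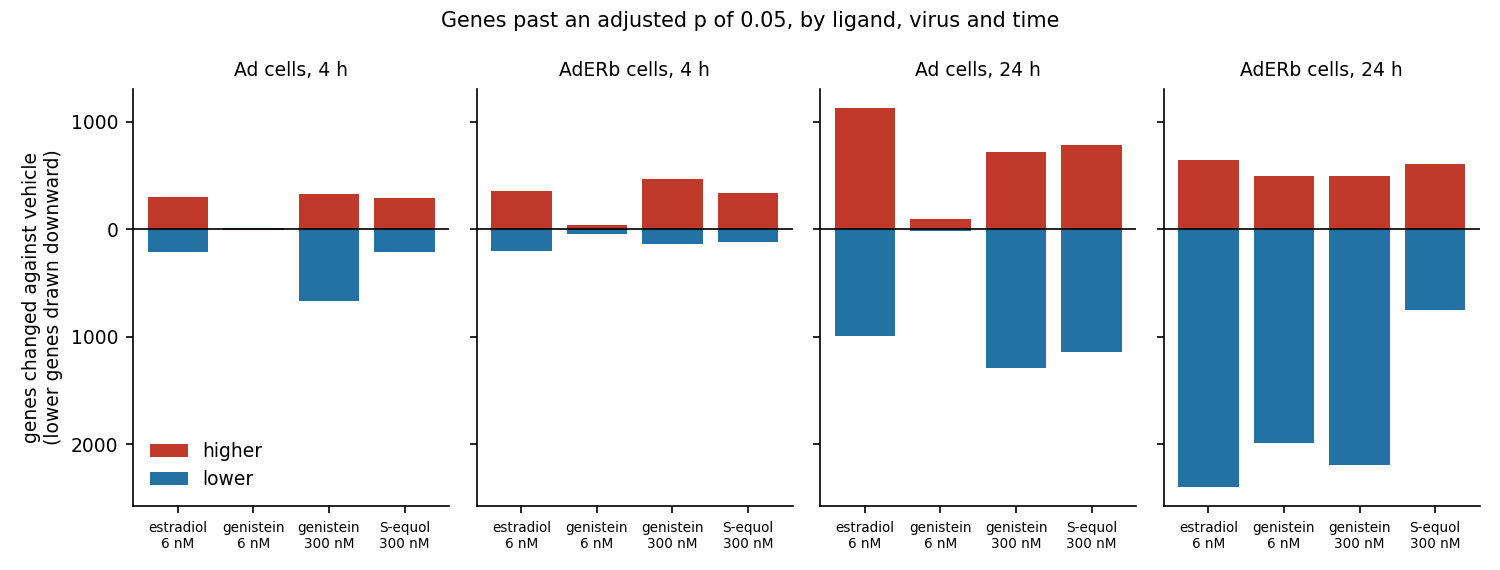
Genes past an adjusted p of 0.05 against vehicle (vertical axis, genes, lower genes drawn downward) for each ligand, by virus and time. In AdERb cells at 24 h estradiol lowered 2398 genes and S-equol 748, and without the level filter estradiol raised 5585 genes and lowered 2613.

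The same ligands were then tested in cells with both receptors. After 4 h in AdERb cells, 560 genes differed, 356 higher and 204 lower with estradiol (3 arrays against 3). With 300 nM genistein 602 genes differed, 465 higher and 137 lower, or 339 and 246 after quantile normalization (3 arrays against 3). With S-equol 448 genes differed, 333 higher and 115 lower, or 255 and 163 after quantile normalization (2 arrays against 3). The count was 217 without AdERb S-equol replicate 1 and 239 without AdERb S-equol replicate 2. IL17RB rose with estradiol (4.72 ± 0.61), 300 nM genistein (4.56 ± 0.61) and S-equol (4.88 ± 0.69). In the same order SERPINB9 rose (4.64 ± 0.29, 4.40 ± 0.29 and 3.99 ± 0.32) and MMD fell (-3.40 ± 0.33, -3.30 ± 0.33 and -3.27 ± 0.37). Of the estradiol-induced list, 19 of 30 members rose and 0 fell (22 and 1 adjusted over the list alone, median 1.285, adjusted p = 5.58e-17) with estradiol. After genistein at 300 nM 25 rose and 0 fell (25 and 0 adjusted over the list alone, median 1.46, 1.37 above that of all genes, adjusted p = 4.97e-22). With S-equol 20 rose and 0 fell (24 and 1 adjusted over the list alone, median 1.34, 1.24 above that of all genes, adjusted p = 6.37e-20). With 6 nM genistein 84 genes differed, 41 higher and 43 lower (3 arrays against 3). That count was 43 without AdERb 6 nM genistein replicate 1, 55 without AdERb 6 nM genistein replicate 2 and 36 without AdERb vehicle replicate 1. P2RY2 (2.06 ± 0.30), HOXC6 (1.85 ± 0.41) and CCND1 (0.88 ± 0.20) rose with 6 nM genistein. Among estradiol-induced genes, 7 of 30 members rose and 0 fell (11 and 1 adjusted over the list alone, median 0.58, adjusted p = 1.02e-11).

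After 24 h in AdERb cells most changed genes among those past the level filter were lower with estradiol and both doses of genistein. With estradiol 3046 genes differed, 648 higher and 2398 lower, or 1468 and 1536 after quantile normalization (6 arrays against 6). With 6 nM genistein 2483 genes differed, 499 higher and 1984 lower, or 1110 and 1145 after quantile normalization (9 against 6). That count was 1193 with the replicate number as a block and 1520 without the low-signal arrays. With 300 nM genistein 2684 genes differed, 493 higher and 2191 lower, or 1237 and 1257 after quantile normalization (4 against 6). With S-equol 1351 genes differed, 603 higher and 748 lower (4 against 6). Within arrays numbered 1 to 3 and those numbered 4 and up, the counts were 1623 and 3100 with estradiol and 1557 and 1845 with 6 nM genistein. Arrays numbered 1 to 3 gave 2245 with 300 nM genistein and 1383 with S-equol. The set numbered 4 and up held a single AdERb array of each of these ligands, so its counts are not given. The median of all genes was -0.29, -0.22, -0.29 and -0.05 in these 4 comparisons. Quantile normalization gives every array the same distribution, which by itself evens such splits. Without the level filter the direction turned: 5585 higher and 2613 lower with estradiol, 4858 and 2228 with 6 nM genistein and 5041 and 2413 with 300 nM genistein. IL17RB rose with estradiol (6.35 ± 0.43), 300 nM genistein (4.87 ± 0.49) and S-equol (5.73 ± 0.49). RRM2 rose with all 4 ligands, by 3.71 ± 0.39, 4.04 ± 0.36, 3.97 ± 0.44 and 4.29 ± 0.44 in the same order. With 300 nM genistein OLFML3 (3.79 ± 0.45), PTTG1 (3.30 ± 0.38) and UBE2C (3.16 ± 0.23) rose. CCNG2 (-3.42 ± 0.52), NBEA (-3.37 ± 0.37), TMEM135 (-3.14 ± 0.43) and IL1R1 (-3.06 ± 0.40) fell. SERPINA3 (4.80 ± 0.25) was among the largest increases with estradiol. TFF1, already higher without ligand, rose with estradiol too (adjusted p = 2.61e-09).

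Of the mitosis list in AdERb cells at 24 h, 23 of 39 members rose and 1 fell (23 and 1 adjusted over the list alone, median 0.61, 0.90 above that of all genes, adjusted p = 1.89e-13, adjusted p = 0.106 with an estimated correlation) with estradiol. With 6 nM genistein 24 rose and 0 fell (27 and 0 adjusted over the list alone, median 0.53, 0.75 above that of all genes, adjusted p = 8.72e-20). After genistein at 300 nM 17 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.50, 0.80 above that of all genes, adjusted p = 1e-14, adjusted p = 0.0679 with an estimated correlation). With S-equol 26 rose and 0 fell (31 and 0 adjusted over the list alone, median 1.02, adjusted p = 2.05e-20). Of the estradiol-induced list, 15 of 30 members rose and 2 fell (15 and 2 adjusted over the list alone, median 0.49, 0.78 above that of all genes, adjusted p = 2.36e-09, adjusted p = 0.106 with an estimated correlation) with estradiol. With S-equol 22 rose and 1 fell (23 and 1 adjusted over the list alone, median 0.89, adjusted p = 5.14e-17). Of the CDK inhibitors and p53 targets, 0 of 10 members rose and 9 fell (0 and 9 adjusted over the list alone, median -1.185, -0.89 from that of all genes, adjusted p = 0.00148, adjusted p = 0.21 with an estimated correlation) with estradiol. After 6 nM genistein 0 rose and 10 fell (0 and 10 adjusted over the list alone, median -0.85, -0.64 from that of all genes, adjusted p = 0.00019, adjusted p = 0.181 with an estimated correlation).

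**Figure D2:**
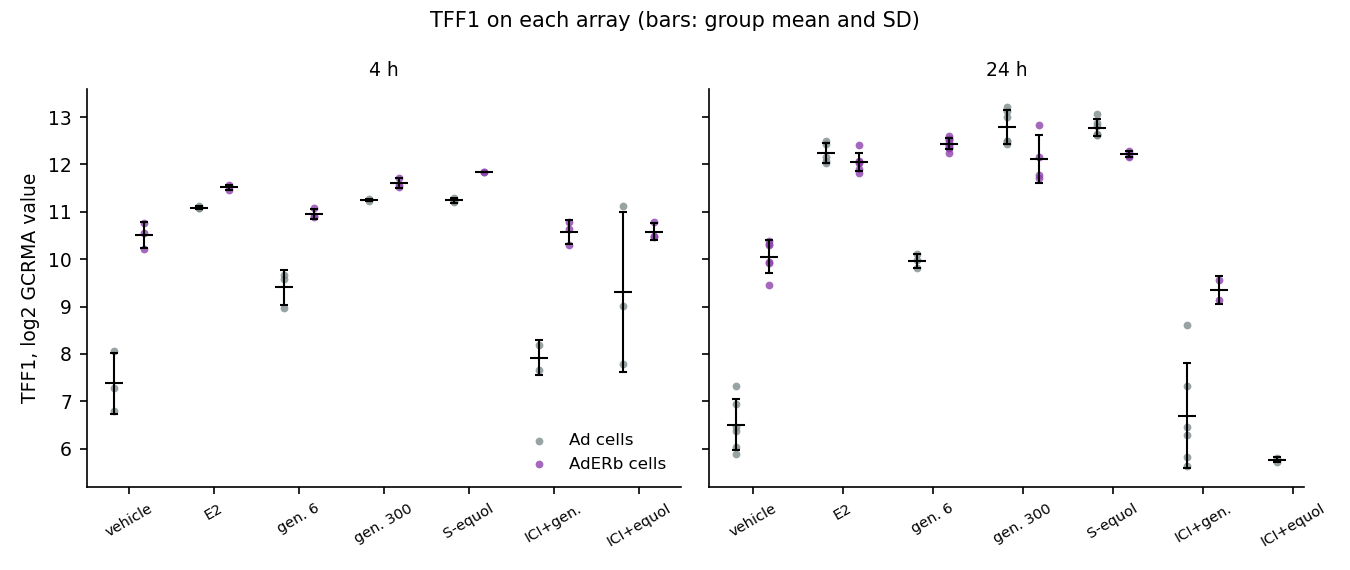
TFF1 on each array (log2 GCRMA value) by treatment and virus, at 4 h and 24 h, with the mean and SD of each group. Vehicle arrays of AdERb cells lay above those of Ad cells at both times, a difference of 3.55 at 24 h, and no AdERb arrays received ICI 182,780 with S-equol at 24 h.

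Interaction terms asked which responses differed between the viruses. At 4 h 7 genes responded differently to estradiol in AdERb cells, 9 to 6 nM genistein, 187 to 300 nM genistein and 5 to S-equol. The count for 300 nM genistein rested on single arrays, as it was 58 without AdERb 300 nM genistein replicate 2, 90 without AdERb 300 nM genistein replicate 3, 88 without AdERb vehicle replicate 2, 90 without AdERb vehicle replicate 3, 413 without Ad 300 nM genistein replicate 1, 19 without Ad 300 nM genistein replicate 2 and 79 without Ad vehicle replicate 2. For estradiol it was 4 without AdERb estradiol replicate 1, 4 without AdERb vehicle replicate 2, 3 without Ad estradiol replicate 1 and 3 without Ad vehicle replicate 3. For 6 nM genistein it was 5 without Ad 6 nM genistein replicate 1, and for S-equol 2 without AdERb S-equol replicate 1, 3 without Ad S-equol replicate 1, 3 without Ad S-equol replicate 3 and 3 without Ad vehicle replicate 3. For 300 nM genistein 168 genes responded more positively in AdERb cells and 19 less, against 53 and 71 after quantile normalization. The median of all genes was 0.24 in that test and 0.13 for S-equol. For estradiol the split was 5 and 2 (4 and 3 after quantile normalization). It was, for 6 nM genistein, 8 and 1 (11 and 6) and for S-equol 4 and 1. SLC10A3 responded more in AdERb cells to each ligand, by 2.08 ± 0.34 for estradiol, 1.83 ± 0.34 for 6 nM genistein, 2.77 ± 0.36 for 300 nM genistein and 2.48 ± 0.36 for S-equol. TFF1 responded less to 300 nM genistein (-2.77 ± 0.57), and the fall of CYP1A1 was smaller (2.14 ± 0.24). The vehicle level of TFF1 was 10.51 in AdERb and 7.38 in Ad cells, and with 300 nM genistein it was 11.6 and 11.24.

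At 24 h the interaction with estrogen receptor beta covered 2265 genes for estradiol, 334 higher and 1931 lower (1000 and 1029 after quantile normalization). For 300 nM genistein 1399 genes differed, 334 higher and 1065 lower, or 790 and 727 after quantile normalization, and for S-equol 385 genes differed, 228 higher and 157 lower. For 6 nM genistein 30 genes were higher and 74 lower, or 90 and 84 after quantile normalization. Its total was 48 without Ad 6 nM genistein replicate 1 and 38 without Ad 6 nM genistein replicate 2, 265 without the numbering set term and 64 with the replicate number as a block. Without the level filter the direction turned to 4996 higher and 2208 lower for estradiol and 3387 and 1263 for 300 nM genistein. The estradiol count was 1153 with the control signal as a term and 1191 without the low-signal arrays. Within arrays numbered 1 to 3 and those numbered 4 and up, 491 and 2340 genes passed for estradiol. Arrays numbered 1 to 3 gave 1365 for 300 nM genistein and 612 for S-equol. The other set held a single AdERb array of each of these ligands, so its counts are not given. The median interaction of all genes was -0.37 for estradiol, -0.16 for 6 nM genistein, -0.22 for 300 nM genistein and 0.00 for S-equol. The mitosis list responded less in AdERb cells. For estradiol 0 rose and 36 fell (0 and 37 adjusted over the list alone, median -2.66, -2.29 from that of all genes, adjusted p = 1.55e-36), where a fall means a smaller response. For 300 nM genistein 0 rose and 36 fell (0 and 36 adjusted over the list alone, median -2.655, -2.43 from that of all genes, adjusted p = 6.87e-43). For S-equol 0 rose and 31 fell (0 and 34 adjusted over the list alone, median -2.05, adjusted p = 1.15e-64). For 6 nM genistein 0 rose and 14 fell (0 and 27 adjusted over the list alone, median -1.03, -0.87 from that of all genes, adjusted p = 1.03e-16, adjusted p = 0.0817 with an estimated correlation). Of the DNA replication list, 0 of 21 members rose and 18 fell (0 and 18 adjusted over the list alone, median -1.49, -1.12 from that of all genes, adjusted p = 9.83e-09, adjusted p = 0.185 with an estimated correlation) for estradiol. KIF2C (-4.42 ± 0.35), CCNA2 (-4.07 ± 0.25), TFF1 (-3.75 ± 0.39) and PRIM1 (-3.56 ± 0.44) responded less to estradiol. S100P (2.52 ± 0.41), SLC10A3 (2.47 ± 0.24) and CCN5 (2.27 ± 0.38) responded more. For S-equol GJA1 (3.69 ± 0.50), IL17RB (3.39 ± 0.65) and SERPINA3 (3.13 ± 0.38) responded more and TFF1 (-4.06 ± 0.41) less. The vehicle level of TFF1 was already 10.05 in AdERb and 6.51 in Ad cells, and with estradiol it was 12.05 and 12.24.

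**Figure D3:**
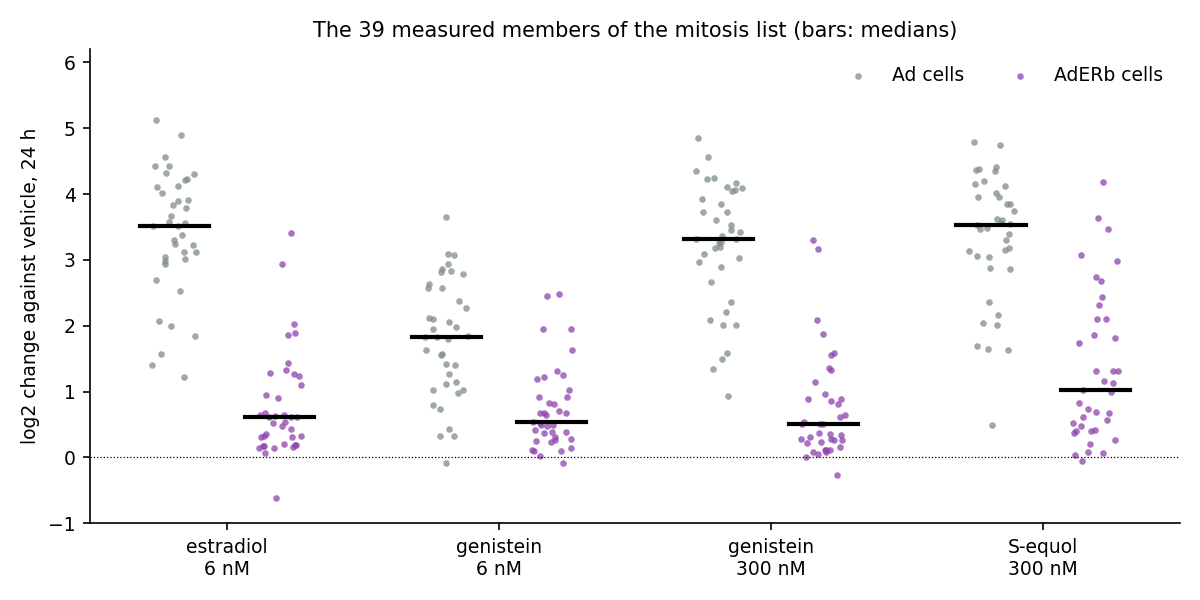
Log2 change against vehicle at 24 h (vertical axis) of the 39 measured mitosis genes (points, bars show medians) for each ligand in Ad and AdERb cells. The median with estradiol was 3.52 in Ad cells and 0.61 in AdERb cells, and with S-equol 3.53 and 1.02.

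Genistein and S-equol at 300 nM were compared directly. In AdERb cells at 4 h limma called 0 genes (3 arrays against 2). There were 70 genes at an unadjusted p under 0.05, 3 past the adjusted threshold without the level filter, and 0 or 1 with 1 array left out. The 95% interval of the difference lay within 2-fold for 4405 of 5005 genes there. In Ad cells at 24 h 4 genes differed, 2 higher and 2 lower with genistein (6 arrays against 6), and the interval lay within 2-fold for 4927 of 5005 genes. TFF1 differed by 0.01 (95% interval -0.53 to 0.55) and GREB1 by 0.54 (95% interval -0.15 to 1.22), both without passing the threshold. In Ad cells at 4 h 40 genes differed, 3 higher and 37 lower, or 3 and 7 after quantile normalization with genistein (2 arrays against 3). The count was 7 without Ad S-equol replicate 1, 5 without Ad S-equol replicate 2, 10 without Ad S-equol replicate 3, 167 without Ad 300 nM genistein replicate 1 and 10 without Ad 300 nM genistein replicate 2. With only the compared groups in the fit it was 0 here and 0 in Ad cells at 24 h, where it was 11 without the level filter. In AdERb cells at 24 h 1583 genes differed, 173 higher and 1410 lower, or 587 and 599 after quantile normalization with genistein (4 arrays against 4), with a median of all genes of -0.26. With the control signal as a term 154 genes differed, 21 of them higher, and without the level filter the direction turned to 3541 higher and 1627 lower. The count was 778 without AdERb S-equol replicate 4 and 879 without AdERb 300 nM genistein replicate 2. Within arrays numbered 1 to 3 and those numbered 4 and up, 53 and 3 genes differed in Ad cells at 24 h. In AdERb cells 1600 did so within arrays numbered 1 to 3, and the other set held a single array of each compound. GREB1 (-1.93 ± 0.42) and STC2 (-1.64 ± 0.30) were lower with genistein by more than that shift.

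**Figure D4:**
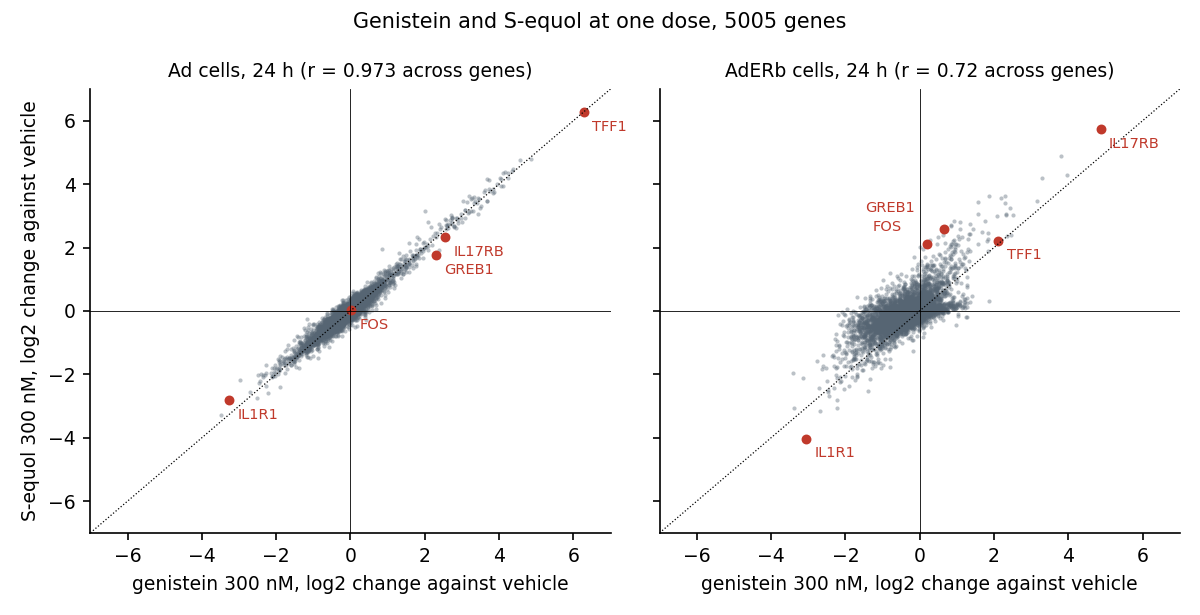
Log2 change against vehicle at 24 h with 300 nM genistein (horizontal axis) and S-equol (vertical axis) for each of 5005 genes, in Ad and AdERb cells, with the line of equal change dotted. The changes correlated with r = 0.973 across genes in Ad cells and r = 0.72 in AdERb cells, where genistein arrays had lower signal.

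At 6 nM, genistein was compared with estradiol. In Ad cells 336 genes differed at 4 h, 98 higher and 238 lower with genistein, and at 24 h 1409 genes differed, 509 higher and 900 lower, or 746 and 796 after quantile normalization. In AdERb cells 131 genes differed at 4 h, 28 higher and 103 lower, and at 24 h 883 genes differed, 671 higher and 212 lower, or 651 and 437 after quantile normalization. That last count was 283 with only the compared groups in the fit and 1658 with the replicate number as a block. Within the 2 numbering sets 962 and 1489 genes differed in AdERb cells at 24 h, and arrays numbered 1 to 3 gave the other direction, 324 higher and 638 lower. Of the mitosis list, 0 of 39 members rose and 39 fell (0 and 39 adjusted over the list alone, median -1.48, -1.41 from that of all genes, adjusted p = 3.52e-23) with 6 nM genistein relative to estradiol in Ad cells at 24 h. In AdERb cells 0 of 39 members rose and 2 fell (0 and 2 adjusted over the list alone, median 0.02, adjusted p = 0.118), and the list did not pass, with a mean below 0 and a camera direction below that of the other genes. It passed with the replicate number as a block and with only the compared groups in the fit. IL17RB was lower with genistein in Ad cells (-4.99 ± 0.55) and in AdERb cells (-4.01 ± 0.40) at 24 h, and IL1R1 was higher (4.52 ± 0.46 and 2.80 ± 0.33). TFF1 differed by -2.19 ± 0.35 in Ad cells and by 0.35 (95% interval -0.14 to 0.85) in AdERb cells, where it did not pass the threshold unless only these groups entered the fit. Its means in AdERb cells were 12.43 with genistein, 12.05 with estradiol and 10.05 with vehicle. In Ad cells they were 9.97, 12.24 and 6.51.

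The dose of genistein was compared as 300 nM minus 6 nM. In Ad cells 317 genes differed at 4 h, 158 higher and 159 lower (184 without Ad 300 nM genistein replicate 2, and 97 higher and 55 lower with only the compared groups in the fit). At 24 h 966 genes differed, 442 higher and 524 lower (642 without Ad 6 nM genistein replicate 3). Among mitosis genes, 34 of 39 members rose and 0 fell (39 and 0 adjusted over the list alone, median 1.26, adjusted p = 8.01e-34) in Ad cells at 24 h. In AdERb cells at 24 h 0 of 39 members rose and 0 fell (0 and 0 adjusted over the list alone, median -0.06, adjusted p = 0.219), and the list did not pass, with a mean below 0 and a camera direction above that of the other genes. It passed with only the compared groups in the fit, with arrays numbered 1 to 3 and without AdERb 300 nM genistein replicate 3. In AdERb cells at 4 h 345 genes differed, 299 higher and 46 lower, or 190 and 113 after quantile normalization, with a median of all genes of 0.12. This count was 205 without AdERb 300 nM genistein replicate 3 and 185 without AdERb 6 nM genistein replicate 1. At 24 h in AdERb cells 67 genes differed, 12 higher and 55 lower, or 46 and 69 after quantile normalization. It was 32 without AdERb 300 nM genistein replicate 1, 23 without AdERb 300 nM genistein replicate 2 and 169 without AdERb 300 nM genistein replicate 3. Within arrays numbered 1 to 3 it was 376, and the other set held a single 300 nM genistein array of AdERb cells. The count was 0 with only the compared groups in the fit, 703 with the replicate number as a block and 433 without the low-signal arrays. Without the level filter it was 71 higher and 52 lower. TFF1 differed by 2.73 ± 0.34 in Ad cells at 24 h and by -0.23 (95% interval -0.80 to 0.34) in AdERb cells, without passing the threshold. Its means in AdERb cells were 12.43 at 6 nM, 12.12 at 300 nM and 10.05 with vehicle. In Ad cells they were 9.97, 12.79 and 6.51, so both doses in AdERb cells lay near the highest level in Ad cells.

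Adding ICI 182,780 asked whether the responses went through the receptors' ligand site. Relative to 300 nM genistein alone, 377 genes differed, 213 higher and 164 lower, or 204 and 247 after quantile normalization in Ad cells at 4 h (2 arrays against 2). That count was 240 without Ad 300 nM genistein replicate 2, 237 without Ad ICI plus genistein replicate 1 and 207 without Ad ICI plus genistein replicate 2, and with only these groups in the fit 46 genes were higher and 64 lower. At 24 h 1988 genes differed, 1143 higher and 845 lower in Ad cells (6 against 6). The count was 2058 and 1041 within arrays numbered 1 to 3 and those numbered 4 and up. In AdERb cells 387 genes differed, 123 higher and 264 lower at 4 h (3 against 3). After 24 h 1270 genes differed, 966 higher and 304 lower, or 698 and 600 after quantile normalization in AdERb cells (2 against 4), with a median of all genes of 0.19 at 24 h. That last count was 528 without AdERb ICI plus genistein replicate 2 and 712 without AdERb ICI plus genistein replicate 1. It was 359 with only the compared groups in the fit and 843 with the control signal as a term. TFF1 fell in Ad cells at 24 h (-6.10 ± 0.27), as did CDC20 (-5.53 ± 0.32) and RRM2 (-4.75 ± 0.39), and IL1R1 rose (3.41 ± 0.36). Of the mitosis list, 0 of 39 members rose and 39 fell (0 and 39 adjusted over the list alone, median -3.435, adjusted p = 7.35e-68) in Ad cells at 24 h. With estrogen receptor beta, at the same time, 0 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.37, -0.56 from that of all genes, adjusted p = 2.99e-10, adjusted p = 0.122 with an estimated correlation). Among estradiol-induced genes, 0 of 30 members rose and 22 fell (0 and 24 adjusted over the list alone, median -1.64, adjusted p = 1.39e-38) in Ad cells at 4 h. For AdERb cells at 4 h 1 rose and 21 fell (1 and 25 adjusted over the list alone, median -1.28, adjusted p = 1.79e-23). For AdERb cells at 24 h 0 rose and 21 fell (0 and 21 adjusted over the list alone, median -1.275, -1.46 from that of all genes, adjusted p = 2.28e-29). Also at that time RRM2 (-6.06 ± 0.58) and IL17RB (-5.12 ± 0.65) fell and CXCL10 (3.81 ± 0.41) rose.

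Relative to S-equol alone, ICI 182,780 changed 491 genes in Ad cells at 4 h, 242 higher and 249 lower (3 arrays against 3). At 24 h 1486 genes differed, 1024 higher and 462 lower, or 818 and 698 after quantile normalization in Ad cells (2 against 6), with a median of all genes of 0.16. The count was 866 without Ad ICI plus S-equol replicate 4 and 815 without Ad ICI plus S-equol replicate 5. In AdERb cells at 4 h 333 genes differed, 108 higher and 225 lower (3 against 2), and the count was 195 without AdERb S-equol replicate 1 and 220 without AdERb S-equol replicate 2. TFF1 (-7.11 ± 0.39) and CDC20 (-5.53 ± 0.45) fell in Ad cells at 24 h. Among mitosis genes, 0 of 39 members rose and 39 fell (0 and 39 adjusted over the list alone, median -3.59, -3.75 from that of all genes, adjusted p = 5.96e-81) at that time. Of the estradiol-induced list, 0 of 30 members rose and 24 fell (0 and 24 adjusted over the list alone, median -1.61, adjusted p = 3.33e-40) in Ad cells at 4 h. For AdERb cells at 4 h 0 rose and 19 fell (0 and 24 adjusted over the list alone, median -1.35, adjusted p = 4.58e-27).

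The responses at 24 h were compared across genes, which are not independent replicates, and all ligands of one virus shared their vehicle arrays. In Ad cells the changes with estradiol and 300 nM genistein correlated with r = 0.941 (rho 0.893, simulated without effects 0.479, median 0.914 over 20 splits of the vehicle arrays). For estradiol and S-equol it was r = 0.937 (rho 0.89, simulated without effects 0.477, median 0.907 over 20 splits of the vehicle arrays). For genistein and S-equol it was r = 0.973 (rho 0.934, simulated without effects 0.502, median 0.94 over 20 splits of the vehicle arrays). In AdERb cells it was r = 0.921 (rho 0.923, simulated without effects 0.448, median 0.887 over 20 splits of the vehicle arrays) for estradiol and 300 nM genistein. There it was r = 0.772 (rho 0.718, simulated without effects 0.45, median 0.743 over 20 splits of the vehicle arrays) for estradiol and S-equol. It was r = 0.72 (rho 0.662, simulated without effects 0.413, median 0.688 over 20 splits of the vehicle arrays) for genistein and S-equol. For the 2 doses of genistein it was r = 0.75 (rho 0.604, simulated without effects 0.4, median 0.668 over 20 splits of the vehicle arrays) in Ad cells. In AdERb cells it was r = 0.932 (rho 0.932, simulated without effects 0.477, median 0.882 over 20 splits of the vehicle arrays). The covariance for genistein and S-equol was 0.484 in Ad cells against a simulated 0.0172, and 0.282 against 0.0179 in AdERb cells. For estradiol and 300 nM genistein it was 0.529 against 0.0172 in Ad cells and 0.439 against 0.0173 in AdERb cells. Of the genes changed by both 300 nM genistein and S-equol in Ad cells, 629 were higher with both (113 for independent lists), 1003 lower with both (295.3) and 0 opposite. In AdERb cells 255 were higher with both (59.4 for independent lists), 648 lower with both (327.4) and 3 opposite. For estradiol and 300 nM genistein in AdERb cells 413 were higher with both (63.8 for independent lists), 1933 lower with both (1049.8) and 3 opposite.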

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

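The tests of explanations in this part were chosen after the results were seen, as were the term for the hybridization controls and the removal of the low-signal arrays. The comparison with other splits of the arrays was planned.

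Panel genes were searched for an array far from the others of its group, in 90 pairs of a gene and a group of 4 to 10 arrays. Chance marks about 1 in 20 such pairs, and 9 were marked. ESR2 read 5.99 on Ad 300 nM genistein replicate 4 at 24 h, 2.96 on Ad S-equol replicate 4 and 2.92 on Ad ICI plus genistein replicate 2. GREB1 read 3.12 on Ad ICI plus genistein replicate 6 and MYC 6.19 on replicate 2 of that group. CXCL12 read 4.31 on Ad vehicle replicate 6. CCNG2 read 4.88 on AdERb S-equol replicate 2, CCND1 8.17 on AdERb 300 nM genistein replicate 1 and CDKN1A 9.66 on AdERb 6 nM genistein replicate 2. The ESR2 value of 5.99 lay above those of all other Ad arrays and below the lowest AdERb array at 11.23. It comes from 1 probe set. The other 2 that detect the transgene read 2.62 and 2.31 on this array, the highest of the Ad arrays but close to background, against at least 8.90 and 8.56 on AdERb arrays, so the value of 5.99 alone does not show ESR2 expression.

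An array outside the comparisons, AdERb S-equol at 4 h by title and ICI plus S-equol by description, read 11.73 for ESR2. This lay within the AdERb range and above the Ad arrays (2.40 to 5.99).

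The response to a ligand differed between Ad and AdERb cells by a test of the difference. At 24 h the numbers of genes with a higher and a lower response in AdERb cells were 334 and 1931 with estradiol, 30 and 74 with 6 nM genistein, 334 and 1065 with 300 nM genistein and 228 and 157 with S-equol. At 4 h they were 5 and 2, 8 and 1, 168 and 19, and 4 and 1 in the same order. Other splits of these arrays were counted but do not test chance for such a difference. A split that exchanges the vehicle and ligand labels in 1 virus adds the 2 responses in place of subtracting them, so its count depends on the responses themselves. The split with the most genes exchanged the labels of all Ad arrays in both 4 h tests, and of most Ad arrays in the 24 h tests of estradiol, 300 nM genistein and S-equol. The splits thus neither exclude chance for these counts nor support it. As many genes as the real split came at 24 h from 1 of 100 splits with estradiol (real 2265, highest other 1980), 3 of 100 with 6 nM genistein (highest other 160 against the 30 and 74 genes above), 3 of 100 with 300 nM genistein (real 1399, highest other 2059) and 9 of 100 with S-equol (real 385, highest other 1293). At 4 h they came from 18 of 100 with estradiol (real 7, highest other 900) and 8 of 100 with 6 nM genistein (real 9, highest other 76). The 4 h tests of 300 nM genistein and S-equol had a group of 2 arrays and were not split.

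The first pattern was the excess of lower genes, among those past the level filter, in AdERb cells at 24 h with estradiol and genistein. Over all genes, without the filter, the excess turned for each of these ligands, as counted above. The share of higher genes among the changed ones was 21.3% with estradiol, 20.1% with 6 nM genistein and 18.4% with 300 nM genistein. The 6 low-signal arrays were not the whole cause: without them the highest of these shares was 26.4%. The hybridization controls read higher with these ligands than with vehicle, by 0.83 ± 0.31, 0.62 ± 0.28 and 0.95 ± 0.35 log2 units, as less RNA from cells on the arrays would give. With the control signal as a term the highest share was 25.1%, which counts against a linear effect of it as the whole cause. An excess of this size with every ligand of estrogen receptor beta is excluded by S-equol, where 44.6% of the changed genes were higher. A narrower range of signal on these arrays stays open and may explain the excess: the 6958 genes below the level filter rose by a median of at least 0.103 while the tested genes fell. Quantile normalization does not separate it from a general fall of transcripts, since it evens the shares in both cases. Such a fall with these ligands and not with S-equol was not tested and stays open as well.

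The second pattern was the smaller rise of mitosis genes with a ligand in AdERb cells than in Ad cells at 24 h. The median interaction of the list was -2.66 with estradiol, -2.66 with 300 nM genistein and -2.05 with S-equol. The shift of all genes in AdERb cells does not account for it, as the highest of the 3 medians was -2.06 after quantile normalization. The numbering sets do not account for it either, since the highest of the 6 medians within a set was -1.85. A higher start level with estrogen receptor beta is excluded, because the list was lower without ligand in AdERb cells, by a median of -0.265. The technical explanations tested were thus excluded, and a hypothesis is that estrogen receptor beta limits the entry into cell division that ligands of estrogen receptor alpha cause. It was found and tested on the same data. Counts of dividing cells after a ligand, in AdERb cells with and without knockdown of estrogen receptor beta, would test it: knockdown should restore the rise. Other differences between the virus preparations stay open, because the labels name no second preparation of either virus.

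The third pattern was the higher level of estradiol-induced genes with estrogen receptor beta before a ligand. The list was higher by a median of 0.573 at 4 h and 0.565 at 24 h. At 24 h a response to the virus that needs no ligand site on a receptor is argued against as the whole cause by ICI 182,780, which with genistein took the list below vehicle in AdERb cells, by a median of -0.73 with 10 of 30 members past the threshold. The median was -0.72 without ICI plus genistein replicate 1 and -0.852 without replicate 2. A candidate explanation at 24 h is receptor activity without added ligand, or with traces of estrogen in the medium, that ICI 182,780 removes. The list fell by more in AdERb than in Ad cells (median -0.03) at 24 h, with a camera adjusted p of 0.0136 (estimated correlation). That difference contains the vehicle difference that made the pattern, so it is no independent test of it. The test rests on 2 AdERb arrays with ICI 182,780, both with genistein. It does not separate activity without ligand from trace estrogen. These 2 arrays also read higher in ESR2, at 13.92 and 13.98 against 12.06 to 13.21 on the AdERb vehicle arrays at 24 h, and on a second probe set at 12.92 and 12.85 against 10.19 to 11.54. An effect of more estrogen receptor beta on the list is thus not separated from that of ICI 182,780. At 4 h ICI 182,780 left the list near vehicle in AdERb cells, at a median of 0.132 with genistein (quartiles -0.03 and 0.27) and -0.028 with S-equol (-0.28 and 0.16), and no member fell past the threshold. In Ad cells these medians were 0.001 and 0.098. A loss of the whole lift within 4 h is thus excluded, and a response to the virus without a ligand site stays open at 4 h, as does receptor activity whose transcripts outlast 4 h of ICI 182,780.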

How the results depend on the processing

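The term for the hybridization controls and the removal of the 6 low-signal arrays were chosen after the data were seen, and all other alternatives were planned. No array had an ESR2 value against its virus label, so the alternative without such arrays was not run. In this part the reported value follows each count in parentheses, and the cause of a move was not tested unless it is given.

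Of the 137 pairs of gene and comparison quoted in the report, 136 kept their direction and their side of the threshold under every alternative run. The exception was TFF1 for 6 nM genistein minus estradiol in AdERb cells at 24 h, which passed with only the compared groups in the fit. The pairs quoted as past the threshold were picked because they kept their call. Of all 2037 pairs the rule named past the threshold, 1282 kept the call and 755 lost it under at least 1 alternative, 26 of them with a reversed direction. Of the 61 list results quoted, 58 kept direction and call under every alternative other than the estimated correlation. The unfolded protein response list with estradiol in Ad cells at 24 h passed without the level filter, and the mitosis list in AdERb cells at 24 h in 3 cases for 300 nM minus 6 nM genistein and 2 for 6 nM genistein minus estradiol. Of all 248 list calls, 177 held and 71 did not, 7 of them reversing under at least 1 alternative. Of the 45 counts of changed genes, 5 stayed within 1.5 times under every alternative run.

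Without the level filter, hence with more genes tested, 15 of 45 counts moved by over 1.5 times, to 42 (17) for 6 nM genistein in Ad at 4 h, 8198 (3046) for estradiol in AdERb at 24 h, 7086 (2483) for 6 nM genistein in AdERb at 24 h and 7454 (2684) for 300 nM genistein in AdERb at 24 h. Others were 32 (7) for the estradiol interaction at 4 h, 17 (9) for the 6 nM genistein interaction at 4 h, 19 (5) for the S-equol interaction at 4 h, 7204 (2265) for the estradiol interaction at 24 h and 60 (30 and 74) for the 6 nM genistein interaction at 24 h. Another was 4650 (1399) for the 300 nM genistein interaction at 24 h. Others were 62 (40) for 300 nM genistein minus S-equol in Ad at 4 h, 11 (4) for 300 nM genistein minus S-equol in Ad at 24 h, 3 (0) for 300 nM genistein minus S-equol in AdERb at 4 h, 5168 (1583) for 300 nM genistein minus S-equol in AdERb at 24 h and 123 (67) for 300 nM genistein minus 6 nM genistein in AdERb at 24 h. After quantile normalization 6 of 45 counts moved by over 1.5 times, to 47 (17) for 6 nM genistein in Ad at 4 h. Others were 17 (9) for the 6 nM genistein interaction at 4 h, 124 (187) for the 300 nM genistein interaction at 4 h and 174 (30 and 74) for the 6 nM genistein interaction at 24 h. Others were 10 (40) for 300 nM genistein minus S-equol in Ad at 4 h and 115 (67) for 300 nM genistein minus 6 nM genistein in AdERb at 24 h. Without the numbering set term 2 of 22 counts moved by over 1.5 times, to 265 (30 and 74) for the 6 nM genistein interaction at 24 h and 931 (1399) for the 300 nM genistein interaction at 24 h. With only the compared groups in the fit 21 of 45 counts moved by over 1.5 times, to 945 (358) for AdERb against Ad vehicle at 4 h, 890 (510) for estradiol in Ad at 4 h, 40 (17) for 6 nM genistein in Ad at 4 h, 608 (1001) for 300 nM genistein in Ad at 4 h and 1069 (560) for estradiol in AdERb at 4 h. Others were 1161 (602) for 300 nM genistein in AdERb at 4 h and 762 (448) for S-equol in AdERb at 4 h. Others were 124 (7) for the estradiol interaction at 4 h, 29 (9) for the 6 nM genistein interaction at 4 h, 287 (187) for the 300 nM genistein interaction at 4 h and 18 (5) for the S-equol interaction at 4 h. Others were 0 (40) for 300 nM genistein minus S-equol in Ad at 4 h, 588 (336) for 6 nM genistein minus estradiol in Ad at 4 h, 152 (317) for 300 nM genistein minus 6 nM genistein in Ad at 4 h, 0 (4) for 300 nM genistein minus S-equol in Ad at 24 h and 219 (131) for 6 nM genistein minus estradiol in AdERb at 4 h. Others were 778 (345) for 300 nM genistein minus 6 nM genistein in AdERb at 4 h, 283 (883) for 6 nM genistein minus estradiol in AdERb at 24 h, 0 (67) for 300 nM genistein minus 6 nM genistein in AdERb at 24 h, 110 (377) for ICI plus genistein minus 300 nM genistein in Ad at 4 h and 359 (1270) for ICI plus genistein minus 300 nM genistein in AdERb at 24 h.

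With the mean of all probe sets of a gene 2 of 45 counts moved by over 1.5 times, to 28 (17) for 6 nM genistein in Ad at 4 h. Another was 15 (9) for the 6 nM genistein interaction at 4 h. With only arrays numbered 1 to 3, hence fewer arrays, 8 of 21 counts moved by over 1.5 times, to 1623 (3046) for estradiol in AdERb at 24 h and 1557 (2483) for 6 nM genistein in AdERb at 24 h. Others were 491 (2265) for the estradiol interaction at 24 h, 375 (30 and 74) for the 6 nM genistein interaction at 24 h and 612 (385) for the S-equol interaction at 24 h. Others were 53 (4) for 300 nM genistein minus S-equol in Ad at 24 h, 1474 (966) for 300 nM genistein minus 6 nM genistein in Ad at 24 h and 376 (67) for 300 nM genistein minus 6 nM genistein in AdERb at 24 h. With only arrays numbered 4 and up, hence fewer arrays, 13 of 17 counts moved by over 1.5 times, to 418 (836) for AdERb against Ad vehicle at 24 h, 1200 (2117) for estradiol in Ad at 24 h, 1045 (2014) for 300 nM genistein in Ad at 24 h, 753 (1927) for S-equol in Ad at 24 h and 1584 (2684) for 300 nM genistein in AdERb at 24 h. Another was 581 (1351) for S-equol in AdERb at 24 h. Others were 389 (1399) for the 300 nM genistein interaction at 24 h and 222 (385) for the S-equol interaction at 24 h. Others were 478 (1583) for 300 nM genistein minus S-equol in AdERb at 24 h, 1489 (883) for 6 nM genistein minus estradiol in AdERb at 24 h, 137 (67) for 300 nM genistein minus 6 nM genistein in AdERb at 24 h, 1041 (1988) for ICI plus genistein minus 300 nM genistein in Ad at 24 h and 929 (1486) for ICI plus S-equol minus S-equol in Ad at 24 h. With the hybridization control signal as a term 7 of 45 counts moved by over 1.5 times, to 37 (17) for 6 nM genistein in Ad at 4 h. Others were 16 (9) for the 6 nM genistein interaction at 4 h, 109 (187) for the 300 nM genistein interaction at 4 h and 1153 (2265) for the estradiol interaction at 24 h. Others were 92 (40) for 300 nM genistein minus S-equol in Ad at 4 h, 154 (1583) for 300 nM genistein minus S-equol in AdERb at 24 h and 843 (1270) for ICI plus genistein minus 300 nM genistein in AdERb at 24 h. Without the low-signal arrays 3 of 10 counts moved by over 1.5 times, to 1520 (2483) for 6 nM genistein in AdERb at 24 h. Another was 1191 (2265) for the estradiol interaction at 24 h. Another was 433 (67) for 300 nM genistein minus 6 nM genistein in AdERb at 24 h.

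In 19 cases an alternative turned the majority of over 10 changed genes to the other direction by more than 10 points of share: 8 without the level filter, 5 after quantile normalization and 2 with only the compared groups in the fit, and 1 each with the mean of all probe sets, with only arrays numbered 1 to 3, with only arrays numbered 4 and up and with the control signal as a term.

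With the replicate number as a block 5 of 45 counts moved by over 1.5 times, to 1193 (2483) for 6 nM genistein in AdERb at 24 h. Another was 64 (30 and 74) for the 6 nM genistein interaction at 24 h. Others were 19 (40) for 300 nM genistein minus S-equol in Ad at 4 h, 1658 (883) for 6 nM genistein minus estradiol in AdERb at 24 h and 703 (67) for 300 nM genistein minus 6 nM genistein in AdERb at 24 h. Of the genes and lists quoted it changed the call of the mitosis list alone, for 6 nM genistein minus estradiol in AdERb cells at 24 h.

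With each array of a group of 2 to 5 left out in turn, hence fewer arrays, the counts that moved by over 1.5 times at least once ran from 189 to 278 (358) for AdERb against Ad vehicle at 4 h, 5 to 11 (17) for 6 nM genistein in Ad at 4 h, 484 to 901 (1001) for 300 nM genistein in Ad at 4 h and 36 to 64 (84) for 6 nM genistein in AdERb at 4 h. Further ranges were 217 to 353 (448) for S-equol in AdERb at 4 h, 3 to 9 (7) for the estradiol interaction at 4 h, 5 to 11 (9) for the 6 nM genistein interaction at 4 h and 19 to 413 (187) for the 300 nM genistein interaction at 4 h. They ran from 2 to 5 (5) for the S-equol interaction at 4 h, 38 to 76 (30 and 74) for the 6 nM genistein interaction at 24 h, 5 to 167 (40) for 300 nM genistein minus S-equol in Ad at 4 h and 184 to 356 (317) for 300 nM genistein minus 6 nM genistein in Ad at 4 h. Further ranges were 642 to 727 (966) for 300 nM genistein minus 6 nM genistein in Ad at 24 h, 0 to 1 (0) for 300 nM genistein minus S-equol in AdERb at 4 h, 185 to 337 (345) for 300 nM genistein minus 6 nM genistein in AdERb at 4 h and 778 to 1648 (1583) for 300 nM genistein minus S-equol in AdERb at 24 h. They ran from 23 to 169 (67) for 300 nM genistein minus 6 nM genistein in AdERb at 24 h, 207 to 452 (377) for ICI plus genistein minus 300 nM genistein in Ad at 4 h, 528 to 1491 (1270) for ICI plus genistein minus 300 nM genistein in AdERb at 24 h and 815 to 866 (1486) for ICI plus S-equol minus S-equol in Ad at 24 h. Further ranges were 195 to 305 (333) for ICI plus S-equol minus S-equol in AdERb at 4 h. Where this left a single array in a group, that array is assumed to vary like the other groups.

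Of the 8 correlations of responses across genes at 24 h, all stayed positive under every alternative run. They moved by more than their spread over splits of the vehicle arrays in 7 of 7 cases with only arrays numbered 4 and up, 3 of 8 with only those numbered 1 to 3, 4 of 8 with the control signal as a term, 2 of 2 without the low-signal arrays, 1 of 8 with the block and 6 of 8 with the vehicle arrays split between the ligands, which removes shared noise. Signal over background limited the number of genes tested: 6958 of 11963 genes lay below the level filter and only the alternative without it speaks of them.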

Other observations

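The splits below were planned, and their comparison with the signal per array was made after the result was seen.

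Chance was excluded by other splits of the same arrays for most 24 h counts. Only the real split gave as many genes for estrogen receptor beta without ligand (1 of 100 splits, real 836, highest other 334). With estradiol, 300 nM genistein and S-equol in Ad cells it was 1 of 100 each time, with real counts of 2117, 2014 and 1927 and highest others of 1781, 1343 and 1397. With 6 nM genistein in Ad cells it was 1 of 84 (real 111, highest other 58). In AdERb cells it was 1 of 100 with estradiol (real 3046, highest other 2086), 300 nM genistein (real 2684, highest other 1984) and S-equol (real 1351, highest other 770). Apart from 6 nM genistein, these highest others kept most or all arrays of 1 group together. They thus nearly repeat or exchange the real split and are not counts of unrelated groupings. With 6 nM genistein in AdERb cells it was 2 of 100 (real 2483), as another split gave 2513 genes. That split exchanged 6 nM genistein replicates 4 and 5 with vehicle replicates 1 and 3. These genistein arrays had 4029 and 3905 genes above the level, against 3429 to 3468 on replicates 7 to 9. The splits thus do not separate 6 nM genistein from the signal of the arrays. As many genes as the real split came from 1 of 56 splits for 6 nM genistein minus estradiol in Ad cells (real 1409, highest other 562). For 300 nM minus 6 nM genistein there it was 1 of 84 (real 966, highest other 804) and for ICI 182,780 with genistein 1 of 100 (real 1988, highest other 1386). For 300 nM genistein minus S-equol in AdERb cells it was 1 of 35 (real 1583, highest other 57). The 300 nM genistein arrays of AdERb cells had 3432 to 3712 genes above the level. All arrays with S-equol (3845 to 3933) and vehicle (3826 to 4136) had more. For these comparisons the real split is also a split by signal, and the splits do not tell the compound from it. With the control signal as a term 154 genes differed between genistein and S-equol.

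Chance was not excluded for 3 comparisons between compounds at 24 h. For 300 nM genistein minus S-equol in Ad cells 34 of 100 splits gave at least the 4 genes called, with a highest other of 445. That split put 2 of the genistein and all 3 of the S-equol arrays numbered 1 to 3 on the same side, so it lay close to the numbering sets, within which 53 and 3 genes differed. For 6 nM genistein minus estradiol in AdERb cells 10 of 100 splits gave as many as the 883 genes called, and the highest other of 2604 put all 5 low-signal arrays of these groups on the same side. For 300 nM minus 6 nM genistein in AdERb cells 20 of 100 splits gave as many as the 67 genes called. Its highest other of 2219 set apart the 4 arrays of these groups with the most genes above the level, 3712 to 4029. These arrays thus differed by signal in a way that the groups do not describe.

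At 4 h the comparisons of 3 arrays with 3 make 10 splits, too few for a share under 0.05. The real split and the highest other gave 358 and 0 genes for estrogen receptor beta without ligand. In Ad cells they gave 510 and 1 with estradiol, 17 and 1 with 6 nM genistein and 499 and 4 with S-equol. In AdERb cells they gave 560 and 1 with estradiol, 84 and 1 with 6 nM genistein and 602 and 0 with 300 nM genistein. For 6 nM genistein minus estradiol they gave 336 and 1 in Ad cells and 131 and 2 in AdERb cells, and for 300 nM minus 6 nM genistein 345 and 3 in AdERb cells. For ICI 182,780 they gave 387 and 25 with genistein in AdERb cells and 491 and 11 with S-equol in Ad cells. Comparisons with a group of 2 arrays were not split.

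The array outside the comparisons read 11.45 for TFF1, 5.39 for GREB1, 3.03 for PGR and 10.27 for ESR1 on the log2 scale. No array was a copy of another: over 5460 pairs of arrays the smallest mean absolute difference was 0.107 log2 units.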
